A study of Homo sapiens with 12 samples.

How the data were processed

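RNA expression was measured in 12 samples of MCF7 cells, each hybridised to 1 Affymetrix whole-transcript array. Per the labels, the cells were transfected at a final oligonucleotide concentration of 100 nM and lysed after 48 h, and each of the 4 groups held 3 biological replicates. The groups were the miR-18a mimic, a mimic negative control, antimiR-18a and a locked nucleic acid (LNA) negative control, taken from the transfection label of each sample. The cells were grown in multi-well plates, and whether wells of 1 number shared a plate or a day was not given in the sources used here.

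The deposited values are on a log2 scale and were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, forces all arrays to 1 distribution of probe intensities and summarises the probes of each probe set. The versions, the annotation level and whether all 12 arrays were normalised together were not given in the sources used here. Because RMA equalises the distributions, a change shared by most transcripts would be removed before deposit, and small values are compressed towards the background, which understates changes of weakly expressed genes. The array medians lay between 3.17 and 3.21 log2, so no further scaling was applied. Arrays have no read depth, and their number limits the precision. All fold changes given here were computed from the deposited log2 values.

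The table held 53617 probe sets. The platform annotation paired 23866 of them with 1 gene symbol, 1852 with several and 27899 with none. Of those with 1 symbol, 22560 matched a gene number in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed through that match. The genome build of the array annotation was not given in the sources used here, so the gene table served only for names, gene lengths and the order of neighbouring genes. Among the probe sets of a gene the one with the highest mean over all 12 arrays was kept, which concerned 630 of 22392 genes. A gene was tested if that mean lay above the median of all probe sets, 3.18 log2, which left 14120 genes.

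All 12 arrays were fitted in 1 model with 4 group means using limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual degrees of freedom per gene and 12.1 after moderation. The contrasts were the mimic minus its control, antimiR-18a minus the LNA control, the difference of those effects, and the LNA control minus the mimic control. P-values were adjusted by the Benjamini-Hochberg method over the 14120 genes, and a gene is said to have risen, fallen or changed only at an adjusted p under 0.05. Every adjusted p of a gene given here is from limma and is two-sided. Standard errors are the moderated ones of that fit.

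Gene lists numbered 24 and were written from general knowledge. They covered reported miR-18a targets, the estrogen response, luminal identity, basal and myoepithelial, mesenchymal, and leukocyte and endothelial markers, mitosis and G2/M, G1/S and DNA replication, the interferon response, p53 targets, the miRNA pathway, TGF-beta signalling, hypoxia and glycolysis, cholesterol biosynthesis, the unfolded protein response, apoptosis, PI3K-AKT-mTOR signalling, the DNA damage response, drug transport and chemotherapy response, histones, ribosomal proteins, mitochondrially encoded genes, small nuclear and nucleolar RNAs, and host genes of miR-17-92 and related clusters. Histones, ribosomal proteins and small RNAs were taken by symbol prefix, so these lists also hold paralogs, pseudogenes and, among the histones, the antisense RNA H1-10-AS1. The 21 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Camera compares the mean test statistic of a list with that of all other genes, so its direction is relative to these and can differ from the sign of the list median.

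The groups, contrasts, gene lists, filter, rule for naming genes and most alternatives were fixed before the data were examined. For the mimic and antimiR comparisons the rule took the 12 genes with the most positive and the 12 with the most negative change among those that passed the test with all 3 treated arrays on one side of all 3 control arrays. Where fewer than 5 passed in a direction, the 5 with the smallest p were given as values. For the control and difference comparisons the rule took 5 each way. All reported miR-18a targets, up to 4 members with the smallest p of every other list, and ESR1, PGR, MKI67, DICER1 and MIR17HG where measured could be named as well.

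The alternatives were a second quantile normalisation, centring each array on its median, no filter or a stricter one on low values (the 70th percentile, 4.43 log2), the mean of the probe sets of a gene, only the 6 arrays of a comparison, a trended robust prior, array weights, replicate number as a block, each array left out in turn, and a minimum change of 1.5-fold. Pooling both control groups, and the histone list without noncoding members, were added after the data had been seen. A planned test of genes with miR-18a seed matches in their 3' untranslated regions was not run, because transcript sequences were not used here.

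The fit was tested on simulated arrays with the real gene means and spreads and 200 changed genes among 14120. In the mimic comparison it recovered 94.0% of changes of 1.5-fold and 31.3% of changes of 1.23-fold, with 6.88% of its calls false. In the antimiR comparison it recovered 80.6% of changes of 1.5-fold and 28.4% of those of 1.23-fold, with 5.44% of calls false. A simulated list of 30 genes shifted by -0.3 log2 was called by camera, and 0 of 100 random lists were. The simulated genes were drawn independently, so this does not show how often camera calls a list of correlated genes by chance. Array weights used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9.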

Results

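MCF7 cells, an estrogen receptor-positive luminal breast cancer line, were transfected with 1 of 4 oligonucleotides and profiled on expression arrays 48 h later. The miR-18a mimic is a synthetic duplex that adds the microRNA, and antimiR-18a is an LNA oligonucleotide that binds and blocks it. Each had its own negative control, and each of the 4 groups held 3 arrays. The series concerns the part that miR-18a plays in breast cancer, and the comparisons show which transcripts differed with the mimic or with antimiR-18a. Array medians lay between 3.17 and 3.21 log2, and any 2 of the 12 arrays correlated at 0.988 to 0.994 across probe sets. The first principal component held 25.8% of the variance and set the 3 mimic arrays apart from all others. The level of miR-18a itself could not be checked. Probe set 16775778, which the annotation pairs with several genes of its host locus, lay at 2.22 ± 0.12 log2 (SD, n = 3) in the mimic control and 2.25 ± 0.03 with the mimic, below the filter.

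Under the miR-18a mimic, genes that estradiol induces in these cells were lower as a group, and so were genes of the cell cycle. The scaffold protein gene PDZK1 was 1.88-fold lower, and GREB1, STC2, CA12 and PGR, the progesterone receptor gene, fell by 0.54, 0.62, 0.48 and 0.53 on the log2 scale. ESR1, which encodes estrogen receptor alpha, differed by -0.02 log2 (SE 0.06) and did not pass the test. Among genes with a probe set listed for them alone, the highest rises were those of CYP4F30P, a pseudogene with related copies nearby, 6.17-fold, and of the lipoprotein receptor gene VLDLR and the glutamate receptor gene GRIK2, 2.63-fold and 2.81-fold. In all, 632 of 14120 genes changed, 332 higher and 300 lower, with all 3 mimic arrays on one side of the 3 control arrays for each of them.

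**Figure D1:**
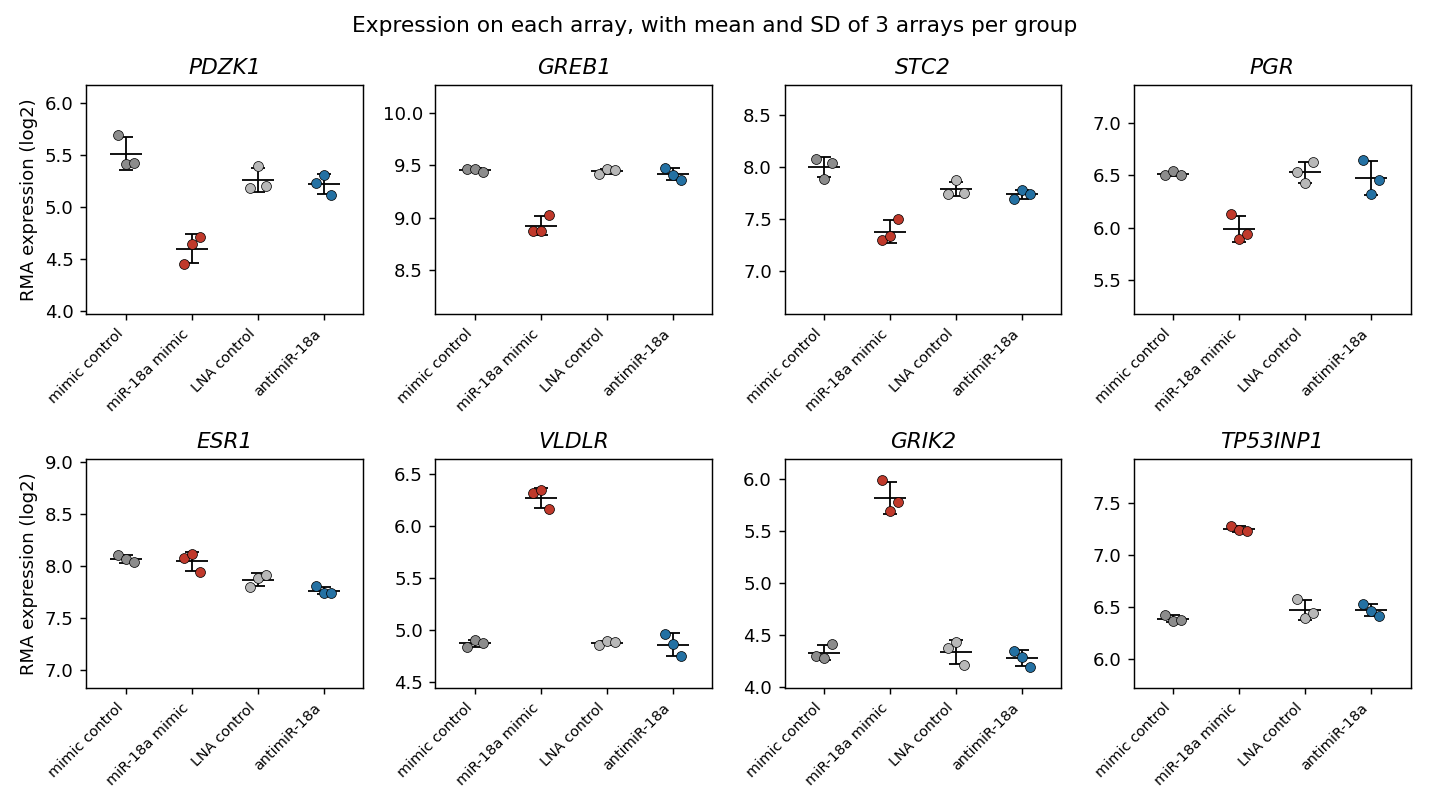
RMA expression (log2) of 8 genes on each array, with horizontal bars for the group mean and whiskers for the SD of 3 arrays; every panel spans the same log2 range around a different centre. PDZK1, GREB1, STC2 and PGR lay lower and VLDLR, GRIK2 and TP53INP1 higher on the mimic arrays than on the mimic control arrays, while ESR1 differed by -0.02 log2.

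Of the estrogen response list, 30 members were tested, of which 17 fell, 0 rose and 13 did not pass (limma's camera, adjusted p = 1.15e-20, and adjusted p = 0.00561 with an estimated correlation). Adjusted over the list alone, 21 fell. The list median was -0.32 log2. PDZK1 (probe set 16669944) had a mean of 4.60 ± 0.14 log2 with the mimic and 5.51 ± 0.16 with its control (SD, n = 3 each; limma, adjusted p = 0.000334). GREB1, an estrogen-induced growth regulator, had means of 8.92 and 9.46 log2 (SE of the difference 0.06, adjusted p = 0.000427), and STC2, a secreted glycoprotein gene, fell to a mean of 7.38 ± 0.11 (SD, n = 3; SE of the difference 0.07, limma adjusted p = 0.000604). The carbonic anhydrase gene CA12 fell with an adjusted p of 0.00146 and PGR with one of 0.00665 in limma.

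Cell-cycle lists moved the same way with smaller changes. All 31 tested genes of mitosis and G2/M were lower in the mean, of which 3 passed and 28 did not (median -0.17 log2, camera adjusted p = 4.46e-12, and adjusted p = 0.0120 with an estimated correlation). Those 3 were CDC20, an activator of the anaphase-promoting complex, NUF2, a kinetochore gene, and the securin gene PTTG1. CDC20 and NUF2 fell by 0.25 and 0.29 on the log2 scale, and PTTG1 lay at 2.99 log2 with the mimic, below the level of the filter, so its change has no exact size. Of 33 tested genes of G1/S and DNA replication 6 fell, 0 rose and 27 did not pass (median -0.18 log2, camera adjusted p = 4.46e-12, and adjusted p = 0.0205 with an estimated correlation). The origin licensing gene CDC6 fell by 0.41 and the primase gene PRIM1 by 0.35 on the log2 scale. Of 26 DNA damage response genes 2 fell and 24 did not pass, with BRCA1 at -0.29 and RAD54L at -0.33 log2 (median -0.15, camera adjusted p = 1.31e-06, and adjusted p = 0.0205 with an estimated correlation). Adjusted over the list alone, 19, 16 and 14 members of these 3 lists fell. Single calls here were fragile: CDC20, NUF2, BRCA1 and RAD54L lost theirs in 6, 9, 6 and 8 of 16 alternatives, CDC6 in 5 of 16 and PTTG1 in 5 of 15, mostly with 1 array left out, while PRIM1 lost it in 0. The proliferation marker MKI67 had a change of -0.18 log2 (SE 0.06, limma adjusted p = 0.0910), which did not pass.

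A further 3 lists passed camera at the preset correlation only. Of 25 p53 targets 3 fell, 1 rose and 21 did not pass (camera adjusted p = 0.00341, and adjusted p = 0.131 with an estimated correlation). TP53INP1, a stress-induced gene tied to cell death and autophagy, rose by 0.86 log2 (SE 0.06, limma adjusted p = 1.9e-05), whereas the repair genes DDB2 and POLH and the metabolic gene TIGAR fell by 0.29, 0.31 and 0.33 on the log2 scale. Of 25 TGF-beta signalling genes 2 rose, TGFB3 by 0.43 and ID3 by 0.47 log2, and 23 did not pass (median 0.09 log2, camera adjusted p = 0.00341, and adjusted p = 0.371 with an estimated correlation). In the LNA control, too, 21 of these 25 genes lay above the mimic control in the mean, with a median of 0.08 log2 that did not pass (camera adjusted p = 0.147). Of 49 ribosomal protein genes only RPL12 fell, by 0.50 on the log2 scale, and 48 did not pass (camera adjusted p = 0.00341, and adjusted p = 0.172 with an estimated correlation). RPL12 was also 0.57 log2 higher in the LNA control than in the mimic control, without passing (limma adjusted p = 0.0806). DDB2 and TIGAR lost their calls in 6 of 16 alternatives each, ID3 in 8 and TGFB3 in 5. Adjusted over the list alone, 8 p53 targets fell and 2 rose, 2 TGF-beta genes rose and 1 ribosomal protein gene fell.

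Reported targets of miR-18a did not pass as a list, with 14 of the 22 tested lower in the mean and a median of -0.03 log2. Of the 22 tested, HIF1A, the hypoxia-inducible factor gene, fell by 0.25 on the log2 scale (SE 0.06, limma adjusted p = 0.0278), the glucocorticoid receptor gene NR3C1 rose by 0.25 log2 (SE 0.06, adjusted p = 0.0440), and 20 did not pass. Those calls ended in 9 and 10 of 16 alternatives, among them leaving out most single arrays. Camera gave an adjusted p of 0.0917 in the lower direction and fry one of 0.0547, and adjusted over the list alone 3 members fell and 1 rose. DICER1, which encodes the nuclease that makes mature microRNAs, differed by -0.13 log2 (SE 0.05, adjusted p = 0.160), CDC42 by -0.20 and PHF19 by -0.28. Changes of SMAD2, SMAD4, THBS1 and TGFBR2 were -0.08, 0.05, 0.01 and 0.06 log2, and none of them passed. ESR1, given above, was also on this list and did not pass.

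The other lists with 5 or more tested members did not pass camera (adjusted p = 0.0917 to 0.939). Luminal identity genes had a median of 0.04 log2 and 1 of 21 rose, the receptor kinase gene ERBB3 (0.30 log2). Basal and myoepithelial markers had 1 rise among 6, the integrin gene ITGB4 (0.40 log2), and mesenchymal markers 1 among 8, the matrix gene SPARC (0.40 log2, from a control level at that of the filter). Mesenchymal markers had a median of 0.04 log2 under the mimic. In the LNA control relative to the mimic control it was 0.24 log2 (camera adjusted p = 0.0572, fry adjusted p = 0.0155). With both control groups pooled SPARC lost its call. Of 17 interferon response genes 2 fell, DTX3L by 0.39 on the log2 scale and the RNA sensor gene IFIH1 to 3.15 log2, just below the level of the filter. Of 30 PI3K-AKT-mTOR genes 3 rose, ERBB4 by 0.66, PIK3R3 by 0.31 and ERBB3, already named, by 0.30 log2. Of 24 apoptosis genes 2 rose, the pro-apoptotic BAK1 by 0.69 and the anti-apoptotic MCL1 by 0.23 log2, and 2 fell, PMAIP1 by 0.45 and CASP8 by 0.39 on the log2 scale. Of 27 hypoxia and glycolysis genes 1 rose, the enolase gene ENO1 (0.34 log2), and 1 fell, HIF1A. Of 18 drug transport genes the efflux pump gene ABCC2 fell, by 0.64 on the log2 scale (limma adjusted p = 0.00243). Among 25 members of the histone list, which holds the antisense RNA H1-10-AS1 and the pseudogene H2BC20P, H2BC21 and H2BC20P rose by 0.38 and 0.34 log2, and both have near-identical copies. Of 168 small nuclear and nucleolar RNAs 1 rose, SNORA50A, and 2 fell, RNU5F-1 and RNU4-4P. No member of the lists of the miRNA pathway (16 genes), cholesterol biosynthesis (18) and the unfolded protein response (24) changed. Among the genes named here, DTX3L, MCL1 and CASP8 lost their calls in 8 or more alternatives, ERBB3 in 6, SPARC and IFIH1 in 5, H2BC20P and RNU5F-1 in 4, PIK3R3, H2BC21 and RNU4-4P in 3 and ENO1 in 1. The median and mean of the miRNA pathway list differed in sign, at -0.02 and 0.00 log2. Adjusted over the list alone, none of these lists had more than 4 members changed in one direction.

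**Figure D2:**
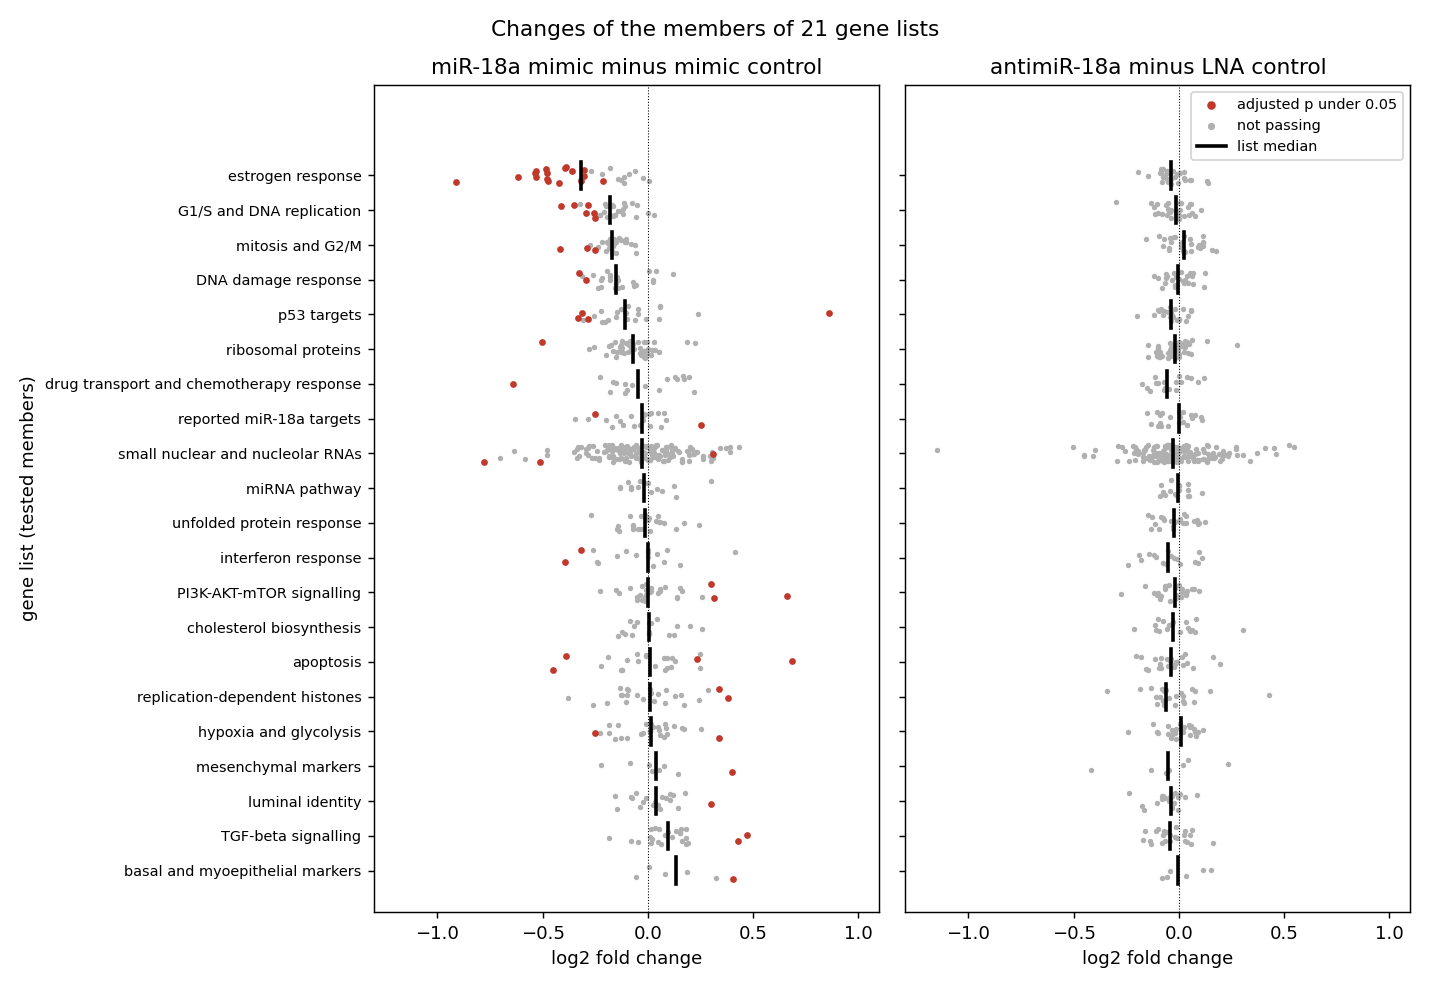
Each point is the log2 fold change of 1 tested member of a gene list, for the mimic minus its control (left) and antimiR-18a minus the LNA control (right); red points had a limma adjusted p under 0.05, and bars mark the list medians. In the left panel 17 of 30 estrogen response genes are red and their median is -0.32 log2; in the right panel no point is red.

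Markers of cell types foreign to the line were few. Of the leukocyte and endothelial markers only CD68, CD79A and EMCN lay above the filter, too few for a list test. EMCN, an endothelial sialomucin gene, rose by 0.44 log2 (limma adjusted p = 0.00329), and CD79A and CD68 differed by 0.25 and -0.20 log2 without passing. Of the host genes of miR-17-92 and related clusters, MCM7, MIR25, MIR93 and MIR106B were tested and none passed, with changes of 0.00, -0.31, 0.02 and -0.08 log2. No mitochondrially encoded gene had a probe set with 1 symbol.

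By size of change, CYP4F30P, GRIK2 and VLDLR were followed by NELL2 and 8 further genes. NELL2 rose by 1.38 log2 (SE 0.13, limma adjusted p = 0.000132), the cadherin gene CDH18 by 1.31, the microtubule-associated MAP1B by 1.13, the membrane peptidase gene MME by 1.07 and the semaphorin gene SEMA3D by 1.07. PCGEM1, a long noncoding RNA, rose by 1.05, the protocadherin gene PCDH7 by 1.04, the metalloproteinase gene MMP16 by 1.01 and the protease inhibitor gene CSTA by 1.01 log2. CYP4F30P had a mean of 6.32 ± 0.32 log2 with the mimic and 3.70 ± 0.11 with its control (SD, n = 3 each; limma adjusted p = 9.53e-05). VLDLR had means of 6.27 ± 0.10 and 4.88 ± 0.03 (adjusted p = 1.11e-06) and GRIK2 of 5.82 ± 0.15 and 4.33 ± 0.07 (adjusted p = 4.13e-06).

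The falls were smaller than the rises. After PDZK1, the probe sets of HLA-DRB1 and HLA-DRB5, which share sequence with other class II genes, lay lower by -0.82 and -0.63 log2. The kinase genes MAP2K6 and JAK2 fell by 0.63 and 0.56, the zinc finger gene ZNF485 by 0.68, the complement receptor gene C5AR2 by 0.60 and TSKU by 0.59 on the log2 scale. The 5S RNA copy RN5S273 was lower by -0.69 log2. The small RNA copy RNU4-4P passed too, but its mean with the mimic, 2.84 log2, lay below the level of the filter, so its change has no exact size and no rank. HLA-DRB5, C5AR2 and RN5S273 lost their calls in 8, 7 and 6 alternatives, TSKU in 3, MAP2K6 in 2 and ZNF485 in 1. A change of at least 1.5-fold was reached by 74 of the 632 genes, 63 higher and 11 lower.

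The count of 632 moved by more than 1.5 times when only the 6 arrays of the comparison were fitted (318 genes), with a trended robust prior (963), and when any 1 of the 6 arrays was left out (306 to 416). Against both control groups pooled, an alternative added after the data had been seen, it was 1117. Of the 62 named genes that passed, 38 to 46 kept their call with 1 array left out.

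Under antimiR-18a 0 genes changed in limma, and the genes with the highest changes under the mimic did not pass here. Whether the oligonucleotide blocked miR-18a in these cells was not measured. On simulated arrays this comparison recovered 80.6% of changes of 1.5-fold and 28.4% of those of 1.23-fold, so small effects may be missed. PDZK1, GREB1, STC2 and PGR differed by -0.04, -0.03, -0.05 and -0.05 log2 between antimiR-18a and the LNA control, with standard errors of 0.10, 0.06, 0.07 and 0.09. VLDLR, GRIK2 and CYP4F30P differed by -0.02, -0.06 and -0.45 log2, and ESR1 by -0.10. Of 14120 genes 0 passed, the smallest adjusted p was 0.450, and 1148 genes had an unadjusted p under 0.05, 8.13% of those tested. The groups did not overlap for 12.7% of genes, where chance gives 10%.

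The genes with the smallest p were higher for PDCD6 (0.43 log2, SE 0.08), MIR548A2, ANKRD36B, PRIMPOL and GAL3ST1, and lower for the interleukin receptor gene IL1R1 (-0.50 log2, SE 0.09), MAPRE3, TNFRSF4, ZNF549 and MIR1229, with limma adjusted p of 0.450 to 0.478. For IL1R1 the unadjusted 95% interval was -0.69 to -0.31 log2, but this gene was picked for its small p and did not pass. The mimic raised IL1R1 by 0.58 log2 (limma adjusted p = 0.00387), and the difference of both effects was 1.08 log2 (limma adjusted p = 0.00143). None of the 22 tested miR-18a targets passed, HIF1A being 0.07 log2 higher (95% interval -0.05 to 0.20) and DICER1 0.00 (95% interval -0.11 to 0.10). Of the 21 lists only mitosis and G2/M passed camera, with a median of 0.02 log2 and 0 of 31 members changed (adjusted p = 0.0241, and adjusted p = 0.955 with an estimated correlation). Its call also ended without a filter on low values, in fry and when any of 4 of the 6 arrays was left out. The median over all genes was -0.02 log2, and for 10 of the 21 lists the median, the mean and the direction of the test differed in sign.

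**Figure D3:**
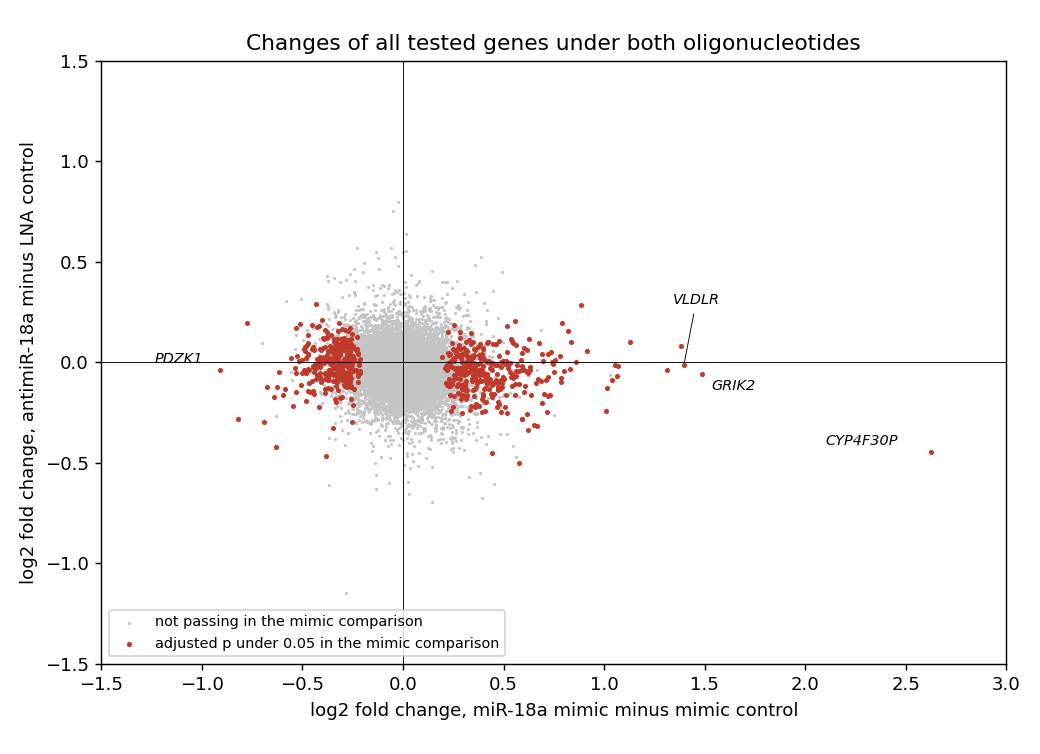
Each point is 1 of 14120 tested genes, with its log2 fold change under the mimic on the horizontal axis and under antimiR-18a on the vertical axis; the 632 genes that passed in the mimic comparison are red. CYP4F30P, GRIK2 and VLDLR lie at 2.62, 1.49 and 1.40 log2 under the mimic and at -0.45, -0.06 and -0.02 under antimiR-18a.

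Whether the effects of the mimic and of antimiR-18a differ was tested directly, as the mimic effect minus the antimiR effect. Here 217 genes passed, 158 with a positive and 59 with a negative difference. The estrogen response list had 6 negative differences and 24 genes that did not pass (median -0.28 log2, camera adjusted p = 1.61e-15, and adjusted p = 0.0110 with an estimated correlation). PDZK1, STC2 and GREB1 were among the 6, at -0.87, -0.57 and -0.51 log2, whereas the difference for PGR, -0.48 log2, did not pass (limma adjusted p = 0.0869). Genes of mitosis and G2/M had 2 negative differences among 31 (median -0.18 log2, camera adjusted p = 3.2e-12, and adjusted p = 0.0110 with an estimated correlation). Of 26 DNA damage response genes 0 passed while the list did (median -0.19 log2, camera adjusted p = 5.78e-06, and adjusted p = 0.0374 with an estimated correlation).

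Calls of G1/S and DNA replication, TGF-beta signalling and ribosomal proteins were lost with an estimated correlation (adjusted p = 0.0669, 0.528 and 0.335), and the other 15 lists did not pass camera. In fry, G1/S and DNA replication passed (adjusted p = 0.00708), and so did luminal identity, in the positive direction (adjusted p = 0.0163). The number of genes with a difference was 115 without a filter on low values, 363 with the stricter filter and 465 with a trended robust prior, and it was 97 without LNA control replicate 3.

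The changes under the 2 treatments were weakly and inversely related across genes. Pearson's r was -0.110 and Spearman's rho -0.113 over 14120 genes, which are not independent replicates. Of 100 relabellings of the arrays within both arms, 3 gave an r as large in size, the real one included, and the largest other was 0.141. Of the 632 genes changed by the mimic, 60.0% had the opposite sign under antimiR-18a, where the other relabellings of the antimiR arm, of 10 in all, gave 40.7% to 59.3%. The median change under antimiR-18a was -0.046 log2 for the genes the mimic raised and -0.00534 for those it lowered, beside -0.0247 for all genes, so the lowered genes did not turn positive in the median. Over those genes r was -0.196 and rho -0.180.

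The control groups, which differ in the chemistry of the oligonucleotide, were compared with each other, and no gene passed. In the LNA control relative to the mimic control, the genes with the smallest p were higher for the small nucleolar RNAs SNORD14E (0.86 log2, SE 0.13) and SNORD4B, the ribosomal protein gene RPL12, the integrin gene ITGB6 (0.61 log2) and EGR1. They were lower for MIR21 (-0.48 log2, SE 0.08), MIR3130-2, ANKRD36B, GAL3ST1 and RN5S440. In limma 0 genes passed, the smallest adjusted p was 0.0806, and 1331 genes had an unadjusted p under 0.05. Ribosomal protein genes were higher as a list, 46 of 49 of them in the mean, with 0 passing over all genes and 12 adjusted over the list alone (median 0.09 log2, camera adjusted p = 5.1e-08, and adjusted p = 0.0627 with an estimated correlation). The histone list was lower, 20 of its 25 members in the mean (median -0.03 log2, camera adjusted p = 0.00241, and adjusted p = 0.259 with an estimated correlation). Without its 2 noncoding members 19 of 23 were lower (median -0.05 log2, camera adjusted p = 0.00103, and adjusted p = 0.275 with an estimated correlation), an alternative added after the data had been seen. Fry called ribosomal proteins (adjusted p = 0.00132), mesenchymal markers (adjusted p = 0.0155) and the unfolded protein response (adjusted p = 0.0261) higher in the LNA control. It did not call the histone list (fry adjusted p = 0.273). With the stricter filter 8 genes differed between the controls, and with a trended robust prior 15.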

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

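No test in this part was chosen after its result was seen, but CYP4F30P was singled out for its size, and the condition on expression level by which the cross-hybridisation test was read was added after its value had been seen. The effects of the mimic and of antimiR-18a differed for 217 genes in the test of the difference itself. The largest positive differences were those of CYP4F30P (3.07 log2), GRIK2 (1.55), VLDLR (1.41), CDH18 (1.35) and NELL2 (1.30). The most negative were those of PDZK1 (-0.87 log2), ANKRD36B (-0.76), FAM72D (-0.72), the cystine transporter gene SLC7A11 (-0.70) and MIR4429 (-0.64). ANKRD36B and FAM72D have near-identical copies, so their values are uncertain. For ANKRD36B the mimic and antimiR effects, -0.34 and 0.42 log2, did not pass singly (limma adjusted p = 0.0568 and 0.478). It was also among the genes named as lower in the LNA control than in the mimic control. A low LNA control alone would make its difference more negative. With each of the 12 arrays left out in turn, MIR4429 lost its call in 11 fits, SLC7A11 in 10 and FAM72D in 4, with differences of -0.72 to -0.54, -0.80 to -0.60 and -0.81 to -0.65 log2 over all 12; the other 7 genes lost none. MIR4429 also lost it without a filter on low values, with array weights and with the replicate block.

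Relabelling bears on these counts to different degrees. Of 100 relabellings of the arrays within both arms, 1 gave as many as 217 genes with a difference, the real one. The highest other gave 118. A share of 1 in 100 argues against chance labels in both arms at once. It does not separate a difference between the effects from an effect of the mimic alone. The 10 drawn relabellings that kept the real mimic labels gave 67 to 217 genes, whichever way the antimiR arm was labelled, and all others gave 0, so much of the count follows the mimic arm. For the mimic comparison 1 of the 10 splits of the 6 arrays, the real one, gave as many as 632 genes, and the highest other gave 1. For antimiR-18a and for the control groups all 10 splits gave as many as the real 0, and the highest other was 0. With 10 splits no share under 0.05 can be reached.

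Probe sets that the annotation pairs with no gene or with several stood outside the comparisons of named genes, and 108 of them changed under the mimic in a limma fit of all 53617 probe sets, 89 with no gene and 19 with several. The highest, probe set 16885625, rose from 3.51 ± 0.32 to 7.17 ± 0.04 log2 (SD, n = 3 each), 12.7-fold, with an adjusted p of 1.22e-05. Probe set 17122676, with no gene, rose by 2.65 log2. Probe set 16902809, listed with the same genes as 16885625, lay at 2.61 ± 0.51 log2 in the mimic control, below the level of the filter, and at 5.36 ± 0.14 with the mimic, so its change has no exact size. Under antimiR-18a only 1 such probe set changed, 17017217, by 1.95 log2 (SE 0.18, adjusted p = 0.0126), from 1.79 to 3.74 log2, although it lay at 2.51 in the mimic control; the lower levels are below that of the filter, so the size is inexact. Between the control groups 4 such probe sets differed.

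The rise of CYP4F30P, a transcribed pseudogene, was the largest among named genes, at 2.62 log2, and probe sets 16885625 and 17117884, listed with several pseudogenes of the same families and region, rose by 3.67 and 1.61 log2, as did 16902809 from a level below that of the filter. Whether these are separate transcripts or 1 signal read by related probes was not tested. The 7 measured FAR and CYP4F genes had a median change of -0.0685 log2, under the bound of 0.2 set to argue against cross-hybridisation from intact relatives. FAR1 and FAR2, both above the filter, differed by 0.06 and -0.14 log2, which argues against those 2 as the source. For the CYP4F genes cross-hybridisation stays open, because only 2 of the 5 lay above the filter. The highest change among these 5 was 0.19 log2, that of CYP4F22. A change of the whole neighbourhood stays open as well, since the 20 nearest tested genes had a median of 0.131 log2, between the bounds of 0.1 and 0.2 set for that test. Of these 20, 5 rose (POTEF, POTEI, POTEE, PTPN18 and LOC440910, by 0.67, 0.60, 0.51, 0.49 and 0.89 log2, named after their values were seen), where 332 of all 14120 tested genes did. The POTE genes are near-identical copies whose rises may be 1 signal, and an effect of the mimic on this region was not tested separately.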

How the results depend on the processing

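Pooling the control groups and leaving noncoding members out of the histone list were chosen only after the data had been seen; all other alternatives were planned. Under the mimic 632 genes changed, and the count stayed within 1.5 times with requantiled or centred arrays, either filter, averaged probe sets, array weights and the replicate block. It was 318 with only the 6 arrays, 963 with a trended robust prior, 1117 with pooled controls and 74 with a minimum change of 1.5-fold; the last counts fewer genes by construction, and for the others the cause was not tested. Left-out arrays gave 306 to 416: 339, 323 and 396 without mimic control replicates 1, 2 and 3, and 306, 350 and 416 without mimic replicates 1, 2 and 3. Of 62 named genes that passed, 62 kept their call after requantiling, 40 with only the 6 arrays and 38 to 46 with 1 array left out; none changed direction. HIF1A, NR3C1, MCL1 and NUF2 lost it in 9 or 10 of 16 alternatives.

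The 217 differences became 115 without a filter, 363 with the stricter filter, 465 with a trended robust prior and 89 at 1.5-fold or more. Left-out arrays gave 97 to 155, within 1.5 times only without mimic control replicate 3 or antimiR-18a replicate 1. The others gave 109 and 113 (mimic control 1 and 2), 98, 116 and 128 (mimic 1, 2 and 3), 110, 109 and 97 (LNA control 1, 2 and 3), and 123 and 121 (antimiR-18a 2 and 3). AntimiR-18a stayed at 0 genes in every alternative run. The controls went from 0 to 8 with the stricter filter, 15 with a trended robust prior, and 0 to 1 with 1 array left out, the 1 without mimic control replicate 2 or LNA control replicate 1.

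Lists that passed under the mimic went from 7 to 4 with an estimated correlation, and those of the difference from 6 to 3. The 1 list of antimiR-18a became 0 with an estimated correlation, in fry and without a filter, and 0 to 1 with 1 array left out, 0 without LNA control replicates 1 or 2 or antimiR-18a replicates 1 or 3. The 2 of the controls became 0 with an estimated correlation, 1 without a filter and 2 to 4 with 1 array left out, 4 without mimic control replicate 1. Leaving noncoding members out of the histone list changed none of these counts. Over the genes changed by the mimic alone, r between both effects was -0.196 instead of -0.110.

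With replicate number as a block the mimic comparison gave 473 genes, antimiR-18a 0, the difference 127 and the controls 0. The arrays gave no sign of a pairing by number, a point the labels leave open. Same-numbered arrays deviated from their group means with correlations of -0.12 to 0.0846, and 1 of 12 arrays matched its own number best. Alternatives for genes with miR-18a sites were not run, for want of transcript sequences. Genes near the background, such as RNU4-4P, limit what small values show.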

Other observations

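The comparisons with the LNA control and with cell-cycle genes were chosen only after the result was seen; the tests of estradiol-repressed genes, gene length and REST targets were set beforehand, but the conditions on spread and level by which the REST test was read were added after its first value had been seen. Of the 632 genes that changed under the mimic, 47 were not listed as protein coding. ITGB6, an integrin gene, rose by 0.82 log2 with the mimic over its control (limma adjusted p = 0.000604) and was also higher in the LNA control than in the mimic control, by 0.61 log2 without passing (adjusted p = 0.0806). MYC, an estrogen-induced gene, was lower with the mimic by -0.48 log2 (adjusted p = 0.0120) and 0.45 log2 higher in the LNA control than in the mimic control (adjusted p = 0.189). Both were singled out after their values were seen.

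The fall of estrogen response genes under the mimic was set against technical explanations. For the list as a whole, mimic control arrays that stand apart are argued against. Its median was -0.319 log2 against the LNA control, beside -0.316 against the mimic control. For single genes the controls did differ, although none passed. All LNA control arrays lay below all mimic control arrays for PDZK1 (at most 5.392 against at least 5.417 log2) and STC2 (7.871 against 7.889). Both falls are thus smaller against the LNA control. ESR1 was likewise lower in the LNA control (at most 7.916 against at least 8.035 log2), and all its mimic arrays (at least 7.945) lay above the LNA control arrays. The estrogen list fell further than 64 cell-cycle genes, with a difference of medians of -0.145 log2 (bootstrap 95% interval over genes, -0.242 to -0.0403). This was the outcome set to argue against the lower cell cycle as the whole cause. It cannot exclude that cause, because genes are not independent replicates and lists may follow 1 cause to different degrees. A candidate explanation is less estrogen receptor activity, and 12 tested genes that estradiol represses had a median of 0.335 log2, at percentile 100 of random lists matched on expression (95% of these between -0.0914 and 0.0889), with 7 risen, among them PSCA (0.54 log2), CCNG2 (0.38) and TXNIP (0.38), examples chosen after their values were seen. The random lists were matched on expression alone, whereas members of a list may move together for any shared cause. Their percentile therefore cannot separate less receptor activity from a lower cell cycle. Less receptor activity remains a hypothesis: it was not measured, and whether the mimic acts on this pathway directly was not tested. ESR1, itself on the list of reported miR-18a targets, did not pass the test. That is an RNA value, and the receptor protein was not measured.

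Several of the highest rises were in very long genes: the 12 highest had a median genomic length of 207 kb, against 24.0 kb for all tested genes, 50.3 kb for those that rose and 36.8 kb for those that fell. This pattern was drawn from those 12 genes, and whether it exceeds chance was not tested. A trend over all genes, with longer genes rising more, is argued against as the cause. Spearman's rho between length and signed change under the mimic was -0.0272 over 13771 genes with a length. For antimiR-18a, where 0 genes changed, it was 0.108. Genes that fell were also longer in the median than all tested genes. A signed rho therefore cannot exclude a link between length and the size of a change. Release of genes silenced by REST, a repressor of neuronal genes, could not be judged: 23 measured REST targets had a median of 0.01 log2, at percentile 50.4 of random lists (95% of these between -0.0445 and 0.0736), where a value of 50 or less had been set to argue against it, and the percentile moved across that bound between random draws. Only 7 of the 23 lay above the filter, so a rise from background may be missed. Other biological explanations were not tested.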
